A study of Mus musculus with 7 samples.

How the data were processed

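Bone marrow mesenchymal stromal cells came from male C57BL/6 mice that were 8 weeks old at the start, per the labels. The mice received an inhibitor of fibroblast activation protein (FAP), here called FAPi, at 500 µg/kg, or the vehicle DPBS, in 100 µl daily for 35 days. The identity of the inhibitor is not given in the sources used here. The series design gives 4 FAPi mice and 3 DPBS mice, and there is 1 library per replicate. Per the labels' protocols, live cells that were positive for Pdgfra and negative for CD45, Ter119 and Tie2 were sorted from limb bones, 7000 cells per sample. Libraries followed a modified Smart-seq2 protocol and were sequenced as paired 150-base reads.

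The authors deposited a gene count table and a CPM table for each library. STAR, HTSeq and the mouse build mm10 are named in the submitters' processing notes, without versions. The annotation and the strand setting of the counting are not given in the sources used here. The names of the deposited count tables carry a tag that reads as removal of duplicate reads, but no protocol describes that step. The deposited counts are whole numbers for 53801 versioned Ensembl gene IDs. The deposited CPM values equal the count divided by the library's total count, scaled to the CPM unit, to within 4.55e-05 CPM. In 6 of the 7 CPM tables the end of the table is repeated, with 2318 to 2340 repeated lines, and the first line per gene was used. Of the gene IDs, 53620 matched GENCODE release M21, which is on the same build, when version suffixes were ignored. Symbols and mm10 coordinates come from that match.

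Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were left out with filterByExpr by group, with its minimum count of 10, which left 12930 genes. Libraries were scaled with TMM factors. Dispersions were estimated with estimateDisp, and the groups were compared with glmQLFit and glmQLFTest with robust settings. The p-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Log2 fold changes are FAPi minus DPBS. The standard error (SE) of a gene was derived from its test, as the absolute log2 fold change divided by the square root of the F statistic. CPM values in the text are TMM-normalised. Total counts ranged from 7492570 to 10569690 per library. A floor of 3 counts corresponds to between 0.284 and 0.400 CPM. Floors and intervals cover counting error only, since reads amplified without molecular identifiers are not independent molecules. Shares of counts in 1 library have 95% Wilson intervals.

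Gene lists, 31 in all, were written from textbook knowledge before the data were examined, as were the tests, the alternatives from the original plan and the rule for naming genes. The 28 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 28 lists. Camera with an estimated correlation, fry, and a two-sided exact permutation test of list means were run beside it. List means are means of log2 CPM with a prior count of 2. With 3 against 4 libraries there are 35 splits, so the smallest exact permutation p is 0.0286. The rule named FAP and its listed relatives, then genes past the threshold with at least 5 CPM on average and separate groups. Where fewer than 5 per direction passed, it filled up to 5 by smallest unadjusted p. It also allowed up to 4 members of each list by smallest p, and the most abundant members of lists of other cell types. A gene that the rule allowed is not reported here.

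The functions were tested on simulated data for the comparison of 4 FAPi with 3 DPBS libraries. Counts for 12930 genes were drawn from the measured means, dispersions and library sizes, with 50 genes changed at each of 4 fold sizes. edgeR recovered 0% of genes changed 2-fold, 26% of those changed 4-fold, 60% of those changed 8-fold and 74% of those changed 16-fold. It called 6 unchanged genes in that simulation and 0 in one with no change. Lowering the interferon list by 1 log2 unit gave an adjusted camera p of 7.59e-16, and 0 other lists were called. Genes were simulated independently of each other, so camera's behaviour with correlated genes was not tested.

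The alternatives were other scalings, filters and tests (DESeq2 1.42.0, limma voom with sample weights, limma on the deposited CPM), 3 covariates or blocks, the omission of each library in turn, and other thresholds and list tests. Correction for transcript length and GC content, and DPBS replicate 3 alone as control, were added after seeing the data. No pair of libraries agreed within sampling noise. Unstranded reads cannot separate a gene from an antisense partner, and near-identical copies share reads, so such genes are marked where they are named. Whether shared reads were counted or dropped was not tested, so the counts of such genes may be incomplete.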

Results

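RNA was measured in sorted bone marrow mesenchymal stromal cells of 3 DPBS-treated and 4 FAPi-treated mice. DPBS replicates 1 to 3 held 9463677, 9228260 and 10569690 gene counts. FAPi replicates 1 to 4 held 7754197, 9226841, 8850004 and 7492570. Totals averaged 9753876 ± 716254 (SD, n = 3) in DPBS and 8330903 ± 838165 (SD, n = 4) in FAPi libraries and did not overlap (two-sided exact permutation p = 0.0571). Genes with at least 1 count averaged 17165 ± 309.9 and 16721 ± 223 (exact permutation p = 0.0857). The 10 most abundant genes took 18.9 ± 0.701% of DPBS and 21.8 ± 1.82% of FAPi counts, also without overlap (exact permutation p = 0.0571), so the gene lists were compared between libraries that differed in these measures on average. The most abundant transcripts were Actb, Igfbp5, Cxcl12, Malat1 and Ibsp. Actb alone took 5.04 ± 0.990% of DPBS and 8.20 ± 2.58% of FAPi counts, with overlap (exact permutation p = 0.0857). The difference in the share of the 10 most abundant genes need therefore not extend beyond this transcript. Cxcl12 encodes the chemokine that retains hematopoietic stem cells, and Ibsp a protein of bone matrix. Spearman correlations across genes ranged from 0.810 to 0.842 between DPBS libraries, from 0.806 to 0.837 between FAPi libraries, and from 0.795 to 0.855 between groups. Genes are not independent replicates, and the correlations between groups overlapped those within groups.

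The design asks how the stromal transcriptome differs after inhibition of FAP, a serine protease of the cell surface. The target transcript, Fap (ENSMUSG00000000392.17, chromosome 2, 62500943 to 62574075, mm10), was present in every library. Its level was 194 ± 19.7 CPM (SD, n = 3) in DPBS and 236 ± 28.5 CPM (SD, n = 4) in FAPi mice. The log2 difference of 0.29 ± 0.23 (SE) did not pass the edgeR test (adjusted p = 0.799). The inhibitor acts on the enzyme, so the transcript level does not measure inhibition. Among relatives of the protease, Dpp4 had a mean of 0.618 ± 0.199 CPM in DPBS and 6.11 ± 6.01 CPM in FAPi mice (adjusted p = 0.520, edgeR). Its DPBS values (0.471 to 0.845 CPM) and that of FAPi replicate 3 (0.582 CPM) lay near the floor of 3 counts. Dpp4 and Dpp8 each overlap an antisense gene. The log2 differences were 0.86 ± 0.66 for Dpp8, 0.85 ± 0.71 for Dpp9 and 0.06 ± 0.64 for Prep. Without FAPi replicate 4 the difference of Dpp8 was 0.21, and without DPBS replicate 3 that of Dpp9 was 1.80. Clec11a, which encodes the bone growth factor osteolectin, differed by 0.39 ± 0.33. The integrin genes Itga11 and Itgb1, whose products form a receptor for osteolectin, differed by -0.07 ± 0.37 and -0.01 ± 0.25. None of the 8 members passed the edgeR threshold, and the list did not pass camera (adjusted p = 0.151).

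No gene passed the edgeR threshold in either direction, with 0 genes higher and 0 lower in FAPi mice among 12930 tested. The smallest adjusted p was 0.0989. At an unadjusted p under 0.05 there were 1053 genes, 576 higher and 477 lower, where uniform p-values give 646.5 and the median over the 35 splits of the 7 libraries is 884. DESeq2 called 84 genes higher and 51 lower, limma voom with sample weights called 1 higher and 0 lower, and limma on the deposited CPM with the same filter called 2 higher and 0 lower. The groups did not overlap at 949 genes, 7.34% of those tested, where chance gives 5.71%.

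The genes named next rank first by unadjusted p in each direction among genes with at least 5 CPM on average and a symbol that is not a predicted or clone name, and are not past the edgeR threshold. Stard8 lies on chromosome X (99003248 to 99074728). Its level was 23.1 ± 11.99 CPM in DPBS and 237 ± 50.4 CPM in FAPi mice, a log2 difference of 3.36 ± 0.42 (adjusted p = 0.0989, edgeR). Ncoa3, a nuclear receptor coactivator (chromosome 2, 165992636 to 166073242), had 121 ± 10.3 and 413 ± 82.0 CPM (log2 difference 1.78 ± 0.25, adjusted p = 0.152). Ncoa3 overlaps Sulf2 on the other strand, and Gon4l overlaps Msto1. Gon4l had 3.14 ± 0.447 CPM in DPBS and 29.9 ± 6.42 CPM in FAPi mice. For Zbtb40 the means were 9.58 ± 3.09 and 72.5 ± 34.4 CPM, and for the splicing factor gene Srsf10 they were 140 ± 20.02 and 385 ± 58.4 CPM. In the other direction, the transcription factor gene Foxp2 (chromosome 6, 14901349 to 15441977) had 91.8 ± 22.7 CPM in DPBS and 22.1 ± 2.85 CPM in FAPi mice. Its log2 difference was -2.05 ± 0.34 (adjusted p = 0.166). Ldah, which encodes a lipid droplet hydrolase, had 324 ± 109 and 62.1 ± 35.3 CPM. Apod, which encodes apolipoprotein D, had 565 ± 88.9 and 215 ± 43.9 CPM. Sdsl had 12.7 ± 3.46 and 0.885 ± 0.304 CPM, and its FAPi values (0.517 to 1.26 CPM) lay near the floor of 3 counts. Lcn2, a neutrophil granule gene that stromal cells can also express, had 115 ± 94.1 and 17.6 ± 8.65 CPM (log2 difference -2.70, and -1.78 without DPBS replicate 2). Each of the 10 ranked genes was separated between the groups and was called by DESeq2. Both follow in part from ranking by p in the same counts, so neither is separate evidence. Over the 35 splits of the libraries DESeq2 called a median of 97 genes.

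**Figure D1:**
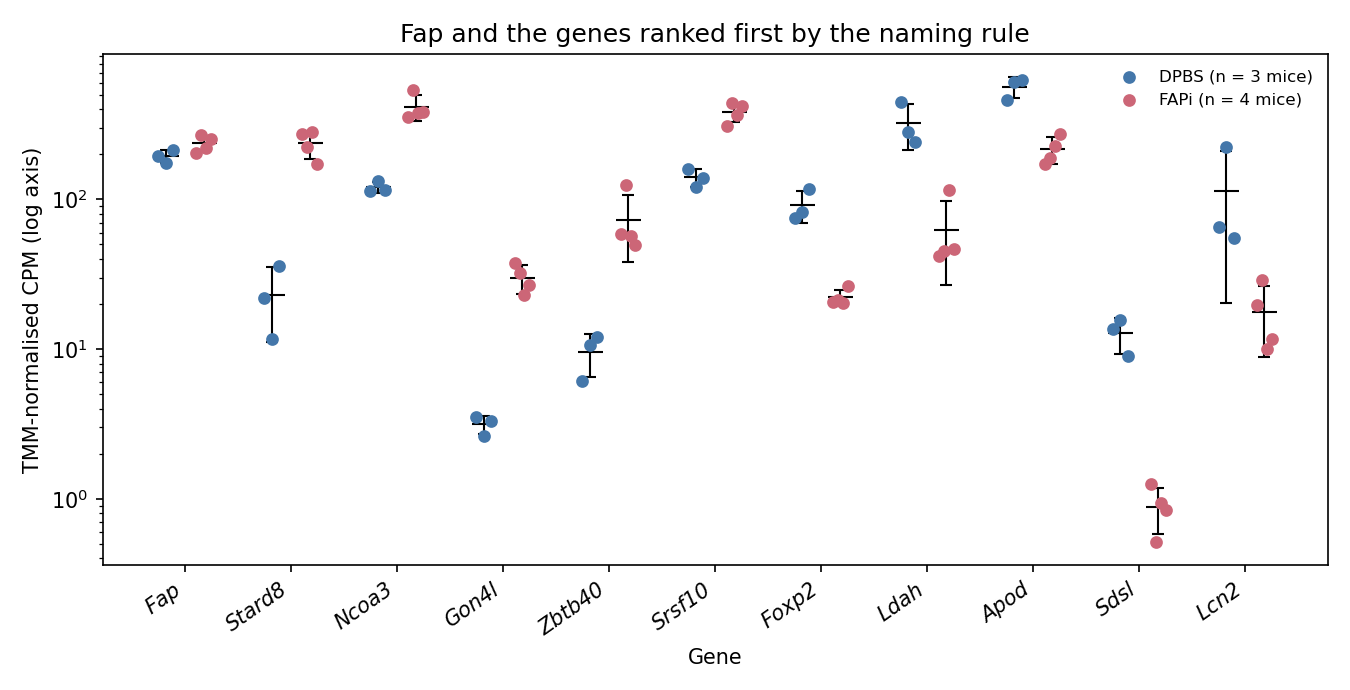
TMM-normalised CPM (log axis) of Fap and of the 10 ranked genes in each library, DPBS in blue (3 mice) and FAPi in red (4 mice), with black bars for the mean and SD. The groups overlap at Fap and are separate at the other genes, which were ranked by p in these same libraries. None of the genes shown passed the edgeR threshold.

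The bone, fat and niche programs of the stroma did not pass the list test. Of 28 tested osteoblast genes, 14 had a higher and 14 a lower estimate (edgeR and camera, adjusted p = 0.969). Bglap, the osteocalcin gene, shares reads with Bglap2 and had 2643 ± 2118 CPM in DPBS and 1095 ± 696 CPM in FAPi mice. Phex and Ifitm5 differed by -0.69 ± 0.36 and -1.36 ± 0.73 on the log2 scale, and Ifitm5 overlaps another gene. Without DPBS replicate 3 the difference of Ifitm5 was -0.69, and that of Bglap was -0.51 against -1.27 with all libraries. Of 18 adipocyte genes, 13 had a lower estimate (adjusted p = 0.651). Adipoq had 1491 ± 121 and 1189 ± 236 CPM, and Apoe 4121 ± 260 and 3388 ± 249 CPM. The log2 differences of Cd36 and Acaca were -0.87 ± 0.45 and 0.88 ± 0.58, and without FAPi replicate 4 that of Acaca was 0.12. The niche list had 21 tested genes (adjusted p = 0.890). Igfbp5 had 53357 ± 5612 and 63208 ± 2497 CPM, and Csf1, a macrophage growth factor gene, 552 ± 39.5 and 676 ± 47.9 CPM. Ly6a, which encodes Sca-1, differed by -0.81 ± 0.40 and Esm1 by -0.28 ± 0.25. None of these members passed the edgeR threshold.

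Signaling lists did not pass either. Canonical Wnt targets had an adjusted camera p of 0.521, with 10 of 14 members estimated higher. Myc had 88.2 ± 14.1 CPM in DPBS and 149 ± 56.1 CPM in FAPi mice. Lef1, which overlaps an antisense gene, and Lgr5 were high in 1 FAPi library each, replicate 1 at 189 CPM and replicate 4 at 57.1 CPM. Without these libraries their log2 differences fell from 3.50 to 0.75 and from 2.06 to 0.94. In the osteoclast regulation list (adjusted p = 0.642), Tnfsf11, which encodes RANKL, had 23.9 ± 2.40 and 95.3 ± 67.8 CPM. Its log2 difference was 1.99 ± 0.57 (adjusted p = 0.483 over all genes, edgeR), and it was the 1 member that passed when adjusted over the list alone. DESeq2 called it over all genes (adjusted p = 0.0369). The groups overlapped at this gene. Sfrp1, a Wnt antagonist gene, differed by 0.53 ± 0.28. Adjusted camera p-values were 0.969 for BMP targets, 0.969 for TGF-beta targets, 0.315 for extracellular matrix genes and 0.846 for chondrocyte genes. Among their members, Id2 differed by 1.46 ± 0.45, Id3 by -0.57 ± 0.24, Col6a3 by 0.83 ± 0.37, Col2a1 by 1.52 ± 0.65 and Sox6 by -2.65 ± 0.89. The difference of Sox6 was -1.27 without DPBS replicate 2, and that of Col2a1 was 2.34 without DPBS replicate 3.

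Camera at the preset correlation called 6 lists as labelled, against a median of 4 over the 35 splits of the 7 libraries. Interferon response genes were lower in FAPi mice as a list. Of 27 tested members 23 had a lower estimate, with a median log2 difference of -0.51 (adjusted camera p = 7.61e-05, and adjusted p = 0.618 with an estimated correlation). The list mean was 5.42 ± 0.122 log2 CPM (SD, n = 3) in DPBS and 4.84 ± 0.279 (SD, n = 4) in FAPi libraries. The groups did not overlap (two-sided exact permutation p = 0.0571, and 0.400 after adjustment). Ifi27 had 242 ± 16.001 and 151 ± 19.2 CPM, Rtp4 181 ± 16.6 and 106 ± 31.7 CPM, and Ifi44 33.1 ± 20.02 and 11.6 ± 3.31 CPM. Rtp4 overlaps another gene on the same strand. Ifi27l2a had 30.3 ± 32.9 and 3.12 ± 0.540 CPM and was the 1 member past the threshold when adjusted over the list alone. No member passed over all genes in edgeR, and DESeq2 called Ifi27l2a (adjusted p = 0.00340). The log2 difference of Ifi27l2a was -3.27, and -1.87 without DPBS replicate 2. Hemoglobin genes, which mark red cells, took 0.225% of counts on average in the same FAPi libraries and 0.797% in DPBS libraries. The fry test for change in either direction gave an adjusted p of 0.0218 for this list, and the directional fry test 0.354.

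Cytosolic ribosomal protein and nuclear oxidative phosphorylation genes were also lower as lists. Of 40 ribosomal protein genes 35 had a lower estimate, with a median log2 difference of -0.31 (adjusted camera p = 7.61e-05, and adjusted p = 0.618 with an estimated correlation). The list mean was 7.89 ± 0.255 log2 CPM in DPBS and 7.57 ± 0.0319 in FAPi libraries (two-sided exact permutation p = 0.0286, the smallest possible, and 0.400 after adjustment). Rpl38 had 354 ± 117 and 187 ± 17.3 CPM, and Rps23 248 ± 51.8 and 150 ± 18.9 CPM. Ribosomal protein genes share reads with pseudogenes. Of 38 oxidative phosphorylation genes 32 had a lower estimate, with a median of -0.32 (adjusted p = 3.36e-04, and adjusted p = 0.618 with an estimated correlation). Atp5d, which overlaps Cbarp, had 103 ± 12.8 and 53.3 ± 9.68 CPM, and Ndufv1 49.8 ± 7.72 and 25.2 ± 9.95 CPM. Without DPBS replicate 2 the adjusted camera p was 0.173 for ribosomal protein and 0.204 for oxidative phosphorylation genes. That library had the highest mean of both lists and of the erythroid and neutrophil lists.

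Cell cycle genes were lower as a list, with 23 of 25 members estimated lower and a median of -0.70 (adjusted camera p = 1.51e-04, and adjusted p = 0.618 with an estimated correlation). The estimated correlation was 0.394, and the two-sided exact permutation p of the list mean was 0.229. DPBS replicate 2 had a list mean of 5.60 log2 CPM, against 3.38 to 4.24 in the other 6 libraries, and without it the adjusted p was 0.639. The same library had the highest erythroid, neutrophil and B cell list means. With the blood marker mean as covariate the cell cycle estimate turned (adjusted p = 0.965). Tpx2, a spindle assembly gene, had 48.6 ± 40.1 CPM in DPBS and 5.98 ± 1.98 CPM in FAPi mice and was called by DESeq2 (adjusted p = 0.0155). The groups overlapped at Tpx2. DPBS replicate 1, at 3.05 CPM, lay below the FAPi libraries (4.47 to 8.85 CPM), and DPBS replicate 3 was highest at 78.2 CPM. Cdc20, which overlaps Elovl1, had 26.1 ± 22.2 and 6.33 ± 2.97 CPM (log2 difference -2.04, and -1.10 without DPBS replicate 2), and Mcm5, a replication helicase gene, 18.5 ± 4.27 and 6.91 ± 2.36 CPM.

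Transcripts of erythroid cells and neutrophils, which the sort against CD45 and Ter119 should remove, were present in every library and lower in FAPi mice. Of 15 neutrophil genes 14 had a lower estimate, with a median of -1.59 (adjusted camera p = 1.21e-08, and adjusted p = 0.618 with an estimated correlation). S100a8 had 1204 ± 729 and 319 ± 140 CPM, and Mmp8 7.24 ± 6.16 and 0.637 ± 0.178 CPM. DESeq2 called both over all genes (adjusted p = 0.0383 and 0.0420). The FAPi values of Mmp8 (0.377 to 0.775 CPM) lay near the floor of 3 counts. Adjusted over the list alone, 3 neutrophil genes were lower. All 15 erythroid genes had a lower estimate, with a median of -1.16 (adjusted p = 6.21e-07, and adjusted p = 0.618 with an estimated correlation). Without DPBS replicate 2 the adjusted p of the erythroid list was 0.126. Hba-a1 had 3817 ± 3476 and 1227 ± 349 CPM, and Hbb-bs 1867 ± 1692 and 549 ± 170 CPM, and both share reads with a near-identical copy. The log2 differences of -1.64 for Hba-a1, -1.77 for Hbb-bs and -3.48 for Mmp8 became -0.64, -0.78 and -2.54 without DPBS replicate 2. Hemoglobin genes took 0.797 ± 0.686% of the counts in DPBS and 0.225 ± 0.0666% in FAPi libraries. DPBS replicate 2 was highest at 1.52% (1.516 to 1.532), and DPBS replicate 3, at 0.162% (0.159 to 0.164), lay within the FAPi range. The interferon list mean of DPBS replicate 3 was 5.28 log2 CPM, against a mean of 4.84 in FAPi libraries. FAPi replicate 2, the highest of them, was close to it at 5.22.

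**Figure D2:**
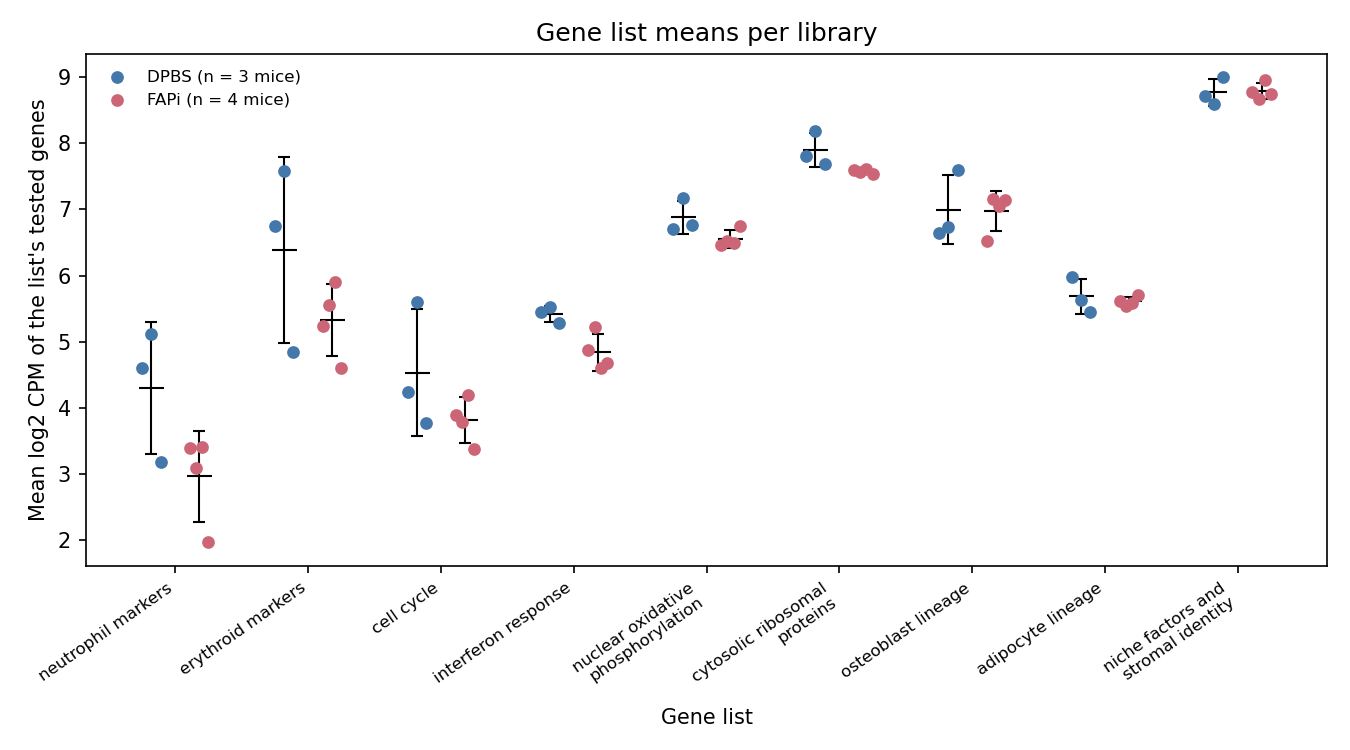
Mean log2 CPM of the tested members of 9 gene lists in each library, DPBS in blue (3 mice) and FAPi in red (4 mice), with black bars for the mean and SD. The interferon and ribosomal protein means of the FAPi libraries all lie below those of the DPBS libraries, while 1 DPBS library lies within the FAPi range for the erythroid and neutrophil lists.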

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

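Within the FAPi group, 99 values were checked for a library far from the other 3, by the gap to its nearest neighbour divided by the range. The check marked 12 values. Chance marks about 1 in 20, or 4.95, if values are independent and normally distributed. Gene values were CPM on a linear scale, every marked gene was marked at its highest library, and list means share members with the genes. The count of 12 therefore does not show an excess over chance. The 3 DPBS libraries were too few for it, and no biological explanation was tested.

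The osteoblast list mean of FAPi replicate 1 was 6.52 log2 CPM, below 7.06 to 7.16 in the other 3 (ratio 0.839). The inflammatory cytokine list mean of FAPi replicate 3 was 5.20, above 4.70 to 4.78 (ratio 0.836). The T and NK cell list, with 1 tested member, stood at 4.46 in FAPi replicate 3, above 0.0852 to 0.436 (ratio 0.920). Lef1 was at 189 CPM in FAPi replicate 1, above 3.77 to 12.8 CPM (ratio 0.951), and Lgr5 at 57.1 CPM in FAPi replicate 4, above 6.17 to 13.9 CPM (ratio 0.848). Acaca was at 87.1 CPM in FAPi replicate 4, above 20.4 to 24.1 CPM (ratio 0.945). Among the ranked genes, Zbtb40 was highest in FAPi replicate 2 at 124 CPM (ratio 0.874), Foxp2 in FAPi replicate 4 at 26.4 CPM (ratio 0.865) and Ldah in FAPi replicate 3 at 115 CPM (ratio 0.932). Cdc20 was highest in FAPi replicate 4 at 10.7 CPM (ratio 0.860), as was Lyz2 at 141 CPM (ratio 0.877). Esm1 was highest in FAPi replicate 1 at 620 CPM (ratio 0.840).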

How the results depend on the processing

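Length and GC correction and DPBS replicate 3 alone as control were added after seeing the data. The edgeR counts of 0 higher and 0 lower genes (1053 at an unadjusted p under 0.05) became 84 and 51 with DESeq2, which left 663 of 12930 adjusted p-values as NA. They became 5 and 1 with no low-count filter (Cdk6, Gm47917, Ncoa3, Stard8, Zbtb40 and, lower, Ldah), 1 higher with voom weights (Stard8), 2 higher with limma on the deposited CPM at either pseudocount (Gm47917, Stard8), 3 lower with DPBS replicate 3 alone (C730045M19Rik, Man1c1, Trpv3) and 1 higher at an adjusted p under 0.1. Leaving out 1 library gave 0 to 2 higher and 0 to 1 lower, the calls coming without DPBS replicate 3 (Gm47917, Stard8 and, lower, Mbnl3). Those outside the naming rule were named after their values were seen. The replicate numbers did not pair the samples (correlations -0.01, -0.02 and -0.05), and the replicate block gave 0 calls and 718 genes at an unadjusted p under 0.05. Deposited CPM without TMM moved the median of all genes by -0.18 at pseudocount 1 and -0.19 at 0.1, and DPBS replicate 3 alone by 0.23 on the log2 scale.

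All 6 list calls ended with an estimated correlation (adjusted p = 0.618 each) and with directional fry (0.354 for interferon, ribosomal protein and neutrophil, 0.355 for oxidative phosphorylation, 0.553 for erythroid and cell cycle genes). The shared 0.618 comes from the adjustment. Before it, camera p with the estimated correlation was 0.0281 for interferon and 0.0533 for neutrophil genes. It was 0.141 for erythroid, 0.187 for ribosomal protein, 0.200 for oxidative phosphorylation and 0.208 for cell cycle genes. Unadjusted exact permutation p was 0.114 for neutrophil, 0.229 for erythroid and for cell cycle, and 0.0857 for oxidative phosphorylation genes. No list passed that test after adjustment (smallest adjusted p = 0.400), which a smallest possible p of 0.0286 makes hard to reach. With the blood marker covariate, which holds the erythroid and neutrophil genes themselves, adjusted p was 0.0530 for neutrophil, 0.554 for erythroid, 0.199 for ribosomal protein and 0.0625 for oxidative phosphorylation genes, and cell cycle genes reversed (0.965). DPBS replicate 3 alone is no check on the blood lists, since it was picked for its low erythroid (4.84 log2 CPM, against 6.75 and 7.57 in the other DPBS libraries) and neutrophil (3.19, against 4.61 and 5.11) means. Its values restate that choice, and the spread comes from the FAPi libraries alone. With it adjusted p was 0.596 for neutrophil, 0.0655 for interferon, 0.661 for ribosomal protein and 0.279 for oxidative phosphorylation genes, with erythroid (0.0696) and cell cycle (0.748) genes reversed. Leaving out 1 library gave 6.08e-09 to 0.639 for cell cycle, 1.58e-04 to 0.204 for oxidative phosphorylation, 3.76e-06 to 0.173 for ribosomal protein and 3.10e-20 to 0.126 for erythroid genes, each highest without DPBS replicate 2. It gave 5.42e-06 to 0.00365 for interferon and 3.66e-16 to 4.66e-04 for neutrophil genes. The B and plasma cell list reversed with the blood covariate (1.19e-07) and without DPBS replicate 2 (0.0196), in a leave-one-out range of 0.0119 to 0.949. Lists not called in the data as reported gained a call in the same direction, at the preset correlation, in 16 cases. These were 4 each for monocyte and macrophage (lowest adjusted p 0.00324), megakaryocyte (2.89e-04) and B and plasma cell markers (4.43e-04), and 1 each for osteoblast and endothelial genes (0.00377 each, with DPBS replicate 3 as a single control), osteoclast markers (0.0249) and the unfolded protein response (0.0452). The osteoblast mean of DPBS replicate 3 was 7.60 log2 CPM, against 6.65 and 6.74 in the other DPBS libraries. Further, 62 of 531 values not called on either side changed direction. The cause was not tested, except that fewer controls enter when libraries are left out.

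Of 1395 gene values under alternatives, 35 changed direction, none of them past the threshold, and 23 passed the threshold in the direction reported. DESeq2 called 15 of the 61 genes, the 10 ranked ones and Tnfsf11, Tpx2, Ifi27l2a, S100a8 and Mmp8. Leaving out 1 library moved 17 genes by over 1.5 times in fold. Without DPBS replicate 2, Lcn2 was at -1.78, Cdc20 -1.10, Ifi27l2a -1.87, Hba-a1 -0.64, Hbb-bs -0.78, Mmp8 -2.54, Sox6 -1.27 and Lef1 4.21. Without DPBS replicate 3, Dpp9 was at 1.80, Bglap -0.51, Ifitm5 -0.69, Col2a1 2.34 and Pf4 -0.28. Without FAPi replicate 4, Dpp8 was at 0.21, Lgr5 0.94 and Acaca 0.12, without FAPi replicate 1 Lef1 at 0.75, and without DPBS replicate 1 Lgr5 at 3.17. Iglc1 also moved without DPBS replicate 2, to 0.12. Prep, with a difference near 0, went to -0.21 with voom weights, -0.15 and -0.17 with deposited CPM at pseudocounts 1 and 0.1, -0.15 without a filter, -0.26 with the replicate block, -0.29 with the genes-detected covariate and -0.11 with length and GC correction, and ranged from -0.26 to 0.42 with 1 library left out. Itga11 went to 0.0022 with voom weights, 0.045 with the block and 0.095 with the genes-detected covariate, and ranged from -0.29 to 0.14. Itgb1 went to 0.020 with DESeq2 size factors, 0.020 with DESeq2, 0.12 with the block, 0.037 with the blood covariate, 0.38 with the genes-detected covariate and 0.12 with DPBS replicate 3 alone, and ranged from -0.10 to 0.12. Dpp8 went to -0.061 with the block and -0.45 with the genes-detected covariate, and Acaca to -0.40 with the latter. With DPBS replicate 3 alone, Dpp9 went to -0.11, Ifi44 to 0.24, Hba-a1 to 0.65, Hbb-bs to 0.52, Esm1 to 0.041 and Sox6 to 0.59. Iglc1 went to 0.14 with the blood covariate and ranged from -3.87 to 0.12, the highest without DPBS replicate 2. The cause was not tested.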

Other observations

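Chosen after the result was seen were the comparison of erythroid with neutrophil list means and the permutation test of both lists together, the length and GC correction, the remaining difference of the ribosomal protein and oxidative phosphorylation lists in SE, and the use of DPBS replicate 3 alone. Per3 and the clock genes were also named after their values were seen.

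Other cell types and processes gave no list call as analysed, though B and plasma cell markers passed in 6 of 25 alternatives, 2 of them in the other direction, monocyte and macrophage and megakaryocyte markers in 4 each, and endothelial and osteoclast markers, osteoblast genes and the unfolded protein response in 1 each. Adjusted camera p-values were 0.121 for monocyte and macrophage, 0.231 for megakaryocyte, 0.521 for B and plasma cell, 0.846 for endothelial, 0.130 for osteoclast and 0.566 for pericyte and smooth muscle markers. Lyz2, an abundant myeloid transcript, had 220 ± 117 CPM in DPBS (SD, n = 3) and 107 ± 23.0 CPM in FAPi mice (SD, n = 4). Pf4, a platelet gene, had 129 ± 105 and 56.4 ± 29.1 CPM (log2 difference -1.20, and -0.28 without DPBS replicate 3). The B and plasma cell list mean was highest in DPBS replicate 2 at 5.72 log2 CPM and in FAPi replicate 1 at 4.82, against 2.16 to 3.06 in the other 5 libraries. Iglc1, which shares reads with other immunoglobulin genes, had 383 ± 603 CPM in DPBS and 38.4 ± 4.37 CPM in FAPi mice (log2 difference -3.32, and 0.12 without DPBS replicate 2). Lists of T and NK cells, skeletal muscle and Schwann cells had 1, 3 and 4 tested members and were not tested. Adjusted p-values were 0.306 for inflammatory cytokines (1 member lower when adjusted over the list alone), 0.969 for immediate early genes, 0.846 for mitochondrially encoded genes, 0.633 for cholesterol synthesis, 0.592 for the unfolded protein response and 0.846 for glycolysis. Of 13 mitochondrially encoded genes 8 were tested. Over all libraries mt-Co2, mt-Co3 and mt-Atp6 held 1, 0 and 13 counts, against 353765 for mt-Cytb. Hsph1, a heat shock gene, had 9.996 ± 4.16 and 28.9 ± 4.10 CPM, Insig1 286 ± 40.8 and 486 ± 169 CPM, and Herpud1 531 ± 52.4 and 879 ± 310 CPM, none past the edgeR threshold.

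The erythroid and neutrophil lists rose and fell together within groups, and carried-over blood cell RNA of varying amount may account for this. The deviations of the 7 libraries from their group means correlated at r = 0.929 (two-sided permutation p = 0.00258) and a Spearman correlation of 0.893 (permutation p = 0.0123). The permutations ran over all 5040 orderings of the 7 libraries, across the groups. Deviations from group means are not exchangeable between groups, so both p-values are approximate and may be too small. Without the 2 libraries farthest from the median, r was 0.865. A difference between treatment groups stays open, with an exact permutation p of 0.2 for the mean of both lists. Chance was not excluded: 5 of 35 splits gave camera p-values as small for both lists (4.44e-08 as labelled, 9.73e-11 as the smallest of the other splits).

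The combined mean of the ribosomal protein and oxidative phosphorylation genes differed by -0.32 ± 0.12 log2 units (SE). After each library's trend over transcript length and GC content was removed it differed by -0.21 ± 0.08 (65.9% of its size, 2.52 SE from 0), with both lists past the threshold (adjusted p = 0.0241 each). It differed by -0.18 ± 0.04 without DPBS replicate 2 (55.5%, 4.55 SE from 0). A difference remained in both cases, but the lists were picked because the labelled split called them, which favours a remainder. Each stays open as a part of the cause, and neither is excluded as the whole. Without that library both calls ended (adjusted p = 0.173 and 0.204) as the difference shrank, while its SE did not grow. With the blood marker mean as covariate the difference was -0.20 ± 0.12 (62.9%, 1.65 SE from 0) and both calls ended (adjusted p = 0.199 and 0.0625), so carried-over blood cell RNA cannot be told apart from other sources of this difference. Over 25 alternatives adjusted p ranged from 3.37e-11 to 0.661 for ribosomal protein and from 2.13e-09 to 0.618 for oxidative phosphorylation genes. Of 35 splits, 1 gave p-values as small for both lists, the labelled one (7.20e-05, against 8.15e-04 as the smallest of the others), but the pair was picked because the labelled split called both lists, so this count does not exclude chance. No biological explanation was tested beyond the treatment groups.

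The lower interferon list kept 86.0% of its difference of -0.58 ± 0.18 log2 units with the blood marker covariate (-0.49 ± 0.22) and 93.4% after the length and GC correction (-0.54 ± 0.17). The length and GC correction took out little of the difference, so the trend that it removed made up little of it. The blood covariate left a smaller difference with a larger SE over 7 libraries, so carried-over blood cell RNA is not excluded. The list was followed up because the labelled split called it, which favours a remainder in both cases. Chance was not excluded, since 2 of 35 splits gave as small a p (1.09e-05 as labelled, 8.05e-07 as the smallest of the others). An effect of the treatment is a hypothesis that stays open.

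The edgeR count of 0 genes in the labelled split (1053 at an unadjusted p under 0.05, 135 called by DESeq2) is reached by all 35 splits by construction, which says nothing about chance, and the highest of the others was 4. At an unadjusted p under 0.05, 5 splits gave at least 1053 genes, with 1162 as the highest of the others and 884 as the median. With DESeq2, 6 splits gave at least 135 genes, with 164 as the highest of the others and 97 as the median. As many as 6 lists were called in 14 splits, with 10 as the highest of the others and 4 as the median. Chance was not excluded for the counts at an unadjusted p, with DESeq2 or of lists. In simulated counts for this comparison over 12930 genes with no change, DESeq2 called 14 genes. With 50 genes changed at each of 4 fold sizes it called 57 unchanged genes.

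Per3, a clock gene, had 761 ± 238 CPM in DPBS and 1805 ± 400 CPM in FAPi mice (log2 difference 1.25 ± 0.28, adjusted p = 0.424, edgeR). Collection at different times of day may shift such genes. Over 13 other clock genes, with the sign turned for those of opposite phase, the median was 0.292. All 8 genes of the first phase were estimated higher, and so were 4 of the 5 of opposite phase, which a shift of phase predicts lower. Many of these estimates lay within their SE of 0, namely Arntl, Cry1 and Clock of the opposite phase and Tef, Nr1d1, Nr1d2 and Ciart of the first. Of the other 2 genes of opposite phase, Npas2 differed by 1.01 ± 0.50 and Nfil3 by -1.72 ± 0.74 (SE). These values do not settle the question.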
